A study of Homo sapiens with 25 samples.

How the data were processed

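MG-63 cells were sampled under 5 conditions (control, 5 or 20 µM FAC, 20 µM DFO, and 20 µM DFO with 20 µM FAC), each in 5 replicates numbered 1 to 5, which gives 25 arrays. Per the labels, the compounds were present for 72 h, and total RNA was amplified and labelled with Cy3 for 1-colour arrays. The deposited scanner files give intensity values per spot, which per the file headers came from Feature Extraction 10.7.1.1 as background-subtracted and spatially detrended signal, with no scaling between arrays. They also give the raw median intensity of each spot and of its local background, and marks for outlier, saturated and well-above-background spots. The deposited series table gives log2 values. A comparison with the scanner files showed that the authors had raised signals under 1 to 1, combined repeated spots and shifted every array to a common median of 5.94. The arrays lay on 13 slides and were scanned on 3 days. The array of DFO with FAC, replicate 2, was outside the quality range given in its own file and was kept.

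The scanner software's signal was used for all main results. Spots marked as outliers were left out (144 to 303 per array) and repeated spots of a probe averaged. Signals were divided by the 75th percentile of their array, floored at 0.001 of it, and put on the log2 scale. Of 34127 gene probes, 24827 carried a RefSeq accession that gave 1 symbol, 0 gave several and 9300 gave none. Probes were kept if well above background on all 5 arrays of at least 1 group, which left 22061, and 20051 were well above it on all 25 arrays. A gene given below as measured on some arrays of a group was well above background on those. Its values on the other arrays still entered the fit. No spot was saturated. With 5 arrays per group, the median SD between arrays of a group was 0.245 on the log2 scale, and 0.172 within replicate numbers.

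Groups were compared in R 4.3.3 with limma 3.58.1, with 1 mean per group, all 25 arrays in the fit and 2-sided moderated t tests (an F test over the 5 groups). p values were adjusted by Benjamini-Hochberg over all kept probes, with a threshold of 0.05. The 7 comparisons were each treatment against control, DFO with FAC against FAC and against DFO, the 2 FAC doses against each other, and the interaction of FAC and DFO was tested as well. Files were read with version 1.17.8 of data.table and figures drawn with matplotlib 3.10.9. These choices, the gene lists, the rule for naming genes and most alternatives were set before the data were examined. Genes named always were HHIPL2, TFRC, FTH1, FTL, HMOX1, ALPL, BGLAP, COL1A1, RUNX2, SPP1, VEGFA, CA9 and NDRG1. Beside them, the rule named at most 12 rises and 12 falls past the threshold, the 10 smallest p values where fewer than 10 genes passed, and up to 4 members of each list with the smallest p. For genes named always, exact permutation tests over the arrays, 2-sided and unpaired, were adjusted over 77 tests.

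The labels number the replicates of each condition and describe them as independent experiments, so the numbers were taken to pair the cultures across conditions if each pair of same-numbered arrays had deviations from their group means correlated at r above 0.1. This held for all pairs among control, both FAC doses and DFO with FAC (lowest r 0.232). It did not hold for DFO alone, whose array 1 correlated at -0.116 to 0.0892 with the other arrays numbered 1. In the comparisons without the DFO group, results with replicate number as a block are therefore given beside those without. The rule did not set same-numbered against other arrays, so it cannot show that single cultures were paired. By mean correlation, 20 of 25 arrays followed their own number best. Control replicate 4 followed number 5 (0.419) above its own (0.399), and FAC 20 µM replicate 1 followed number 2 (0.4165) above its own (0.3757). No number had its control and its 20 µM FAC array scanned on the same day, so differences within scan days also hold differences between numbers, and medians of lists are also given within numbers. The block lowered the median residual SD by 30.0%. Adding the block and leaving out DFO replicate 1 together lowered it by 36.2%, both against all 25 arrays without the block.

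Gene lists were written by hand and hold 33 groups: iron import, iron storage and export, iron-sulfur clusters and haem, hypoxia targets, glycolysis, iron-dependent dioxygenases, osteoblast genes, hedgehog, matrix, matrix proteases, Wnt, TGF-beta and BMP, proliferation, DNA replication, p53 targets, NRF2 targets, metallothioneins, integrated stress response, heat shock, respiratory chain, cholesterol, fatty acids, inflammation, interferon, immediate early genes, apoptosis and ferroptosis, growth factors, adipocyte, chondrocyte, smooth muscle, leukocyte and epithelial markers, ribosomal proteins and housekeeping genes. They were tested with camera from limma on 1 probe per gene, the brightest, at a preset inter-gene correlation of 0.01, with lists of at least 5 measured genes and adjustment over lists within a comparison. camera asks whether a list moves against all other genes. Both this test and limma's fits were tested on simulated data. With a true log2 change of 0.5, 1 or 2 the fit without a block recovered 25%, 82.5% and 95% of changed probes with 0 false calls, and the block fit 68.3%, 95% and 96.7% with 6 false calls. A list shifted by 0.3 was found by camera with either correlation and by fry, with 0 other lists called. Apart from the number effects, the simulated noise was independent between probes, and every simulated array followed its number. False calls from correlated genes of a list, or from DFO replicate 1, could therefore not be shown.

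Alternatives for probes and genes were quantile scaling, centring on each median, normexp background correction (offset 50), the series table, no filter, a filter on all 25 arrays, outlier spots kept, 1 probe per gene, a replicate block, slide as a fixed or random block, scan day as a block, a trended robust prior, array weights, only the arrays compared, and each array left out in turn. normexp used the raw median signal, since the files hold no mean signal. For lists they were an estimated correlation, fry, the mean of all probes, quantile scaling and a replicate, slide or scan-day block. Those chosen after the data were seen left out DFO replicate 1, DFO with FAC replicate 2 or the DFO group, with or without the block, or joined the replicate block to an estimated correlation, a scan-day block or only the arrays compared, or set a scan-day block for lists. The raw background signal and control spots were left out of the comparisons, except that the normexp correction used both. No batch was removed from the values.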

Results

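Gene expression was measured in 25 cultures of MG-63 cells, a human osteosarcoma line with osteoblast-like properties, kept for 72 h in 5 conditions. Ferric ammonium citrate (FAC) supplied iron at 5 or 20 µM. Deferoxamine (DFO), an iron chelator, was given at 20 µM alone or together with 20 µM FAC, and control cultures received neither. Each condition had 5 biological replicates, which the labels describe as independent experiments, and each culture had its own 1-colour array. On every array 43118 spots carried gene probes, and 65.2% to 72.5% of them were well above background. The 75th percentile of the signal ran from 787 to 1076 intensity units. The number of arrays limits the precision. Of 34127 gene probes, 22061 were tested, and 18041 of these belonged to 14066 genes with a symbol. Of 34 osteoblast genes on the array, 23 were well above background on all 25 arrays, among them BGLAP, COL1A1 and SPARC. SPP1, IBSP and OMD were above it on none, and ALPL on all arrays of no group. The arrays differed strongly by replicate number, with 12500 of 21940 probes differing between numbers in limma. The first principal component (25.8% of the variance) followed the number (R2 0.85) more than the treatment (R2 0.027).

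The series asked how iron excess changes osteoblast-like cells, with HHIPL2, of the hedgehog-interacting protein family, in its title. At 20 µM FAC, TFRC, the transferrin receptor that takes up iron, fell by 2.06 on the log2 scale against control (SE 0.32, n = 5 per group). It was lower in 5 of 5 replicate numbers and went from 1.44 ± 0.26 (SD) to -0.62 ± 0.43 relative to the 75th percentile of each array. HHIPL2 fell by 1.46 (SE 0.18), also lower in 5 of 5 numbers, from -3.52 ± 0.26 to -4.98 ± 0.43. GFPT2, a rate-limiting enzyme of hexosamine synthesis, fell by 0.57 (SE 0.091). FOLR3, of the folate receptor family, rose by 0.83 (SE 0.14), and TMEM97, the sigma-2 receptor, rose by 0.29 (SE 0.052).

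These calls came from limma with replicate number as a block, which called 10 of 22061 probes (4 up, 6 down). The adjusted p was 0.0136 for TFRC, 0.00193 for HHIPL2, 0.0201 for GFPT2, 0.0246 for FOLR3 and 0.0490 for TMEM97. The other 5 were 4 probes without a symbol and a GPR155 probe (-0.57), named after its values were seen, while the brightest GPR155 probe stood at 0.14. TFRC lies on chromosome 3 at 196049284 to 196082090 and HHIPL2 on chromosome 1 at 222522264 to 222548104 (GRCh38). Without the block limma called 0 probes (587 at an unadjusted p under 0.05), with adjusted p = 0.0633 for both TFRC and HHIPL2. In exact permutation tests over the arrays (two-sided, no pairing) TFRC and HHIPL2 each gave p = 0.00794, the smallest that 5 against 5 allows, and 0.102 adjusted over the 77 tests of that family. Within the 3 scan days TFRC stood -2.72, -1.78 and -1.67 from control and HHIPL2 -0.93, -1.85 and -1.29. No replicate number had its control and its 20 µM FAC array scanned on the same day, so values within days also hold the differences between numbers. With number and scan day as blocks together, chosen after the data were seen, limma called 4 probes, with HHIPL2 at -1.43 (adjusted p = 0.000195) and TFRC at -2.05 (adjusted p = 0.0289).

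Over all alternatives, most of them without the block, the adjusted p of HHIPL2 at 20 µM FAC ran from 0.000195 to 1. The latter came with normexp background correction and no block (-0.72). The adjusted p of TFRC ran from 0.00673 to 0.373. With the 10 compared arrays alone the block fit called 1 probe.

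An array of the DFO group, replicate 1, did not follow its replicate number. With the replicate block and without that array, limma called 161 probes at 20 µM FAC (73 up, 88 down; 137 genes), the 10 probes above among them. That fit was chosen after the data were seen. In it CSF2, the granulocyte-macrophage colony-stimulating factor, rose by 2.00 (SE 0.34, well above background on 4 of 5 control arrays, with all 5 in the fit). SPNS2, a sphingosine-1-phosphate transporter, rose by 1.18 (SE 0.26). HMOX1, which degrades haem, rose by 0.94 (SE 0.16), and FTL, the ferritin light chain that stores iron, by 0.46 (SE 0.078). All 4 were higher in 5 of 5 numbers. ABCA13 (0.90), C10orf90 (0.74), KRT32 (0.72), FGF11 (0.70, measured on 3 of 5 control arrays), MYEOV (0.69), PAG1 (0.68), KCNK12 (0.61), PRDM1 (0.57) and the collagenase MMP1 (0.52) rose as well. The interferon-inducible genes TRIM22 (-0.78), MX2 (-0.67) and RTP4 (-0.60) fell, as did the prostaglandin E2 receptor PTGER2 (-0.63) and the matrix gene MATN2 (-0.64). PCDH10 (-0.94, measured on 3 of 5 arrays with FAC), MYOC (-0.86), SLC9A9 (-0.71), PCDH7 (-0.63) and PRDM6 (-0.62) fell too.

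In this fit the adjusted p was 0.0118 for CSF2, 0.0103 for HMOX1, 0.0108 for FTL and 0.000576 for PTGER2. Over all alternatives the adjusted p of the 26 genes named for passing ran from 0.000195 to 1, and in 11 of them some alternative lowered the change by over 1.5 times. Most alternatives had no replicate block, and without it limma called 0 probes here. The upper end of the adjusted p can therefore not be put down to the processing alone. With normexp FGF11 turned to -0.053, and PRDM1 stood at 0.086, PCDH7 at -0.32, PCDH10 at -0.36, ABCA13 at 0.39, MATN2 at -0.40, MYEOV at 0.41, FOLR3 at 0.45 and CSF2 at 0.92. HMOX1 stood at 0.53 with slide as a fixed block. Ferritin heavy chain FTH1 (0.06), BGLAP (0.17), COL1A1 (-0.28), RUNX2 (0.16, measured on 4 and 3 arrays), VEGFA (0.45), CA9 (0.20) and NDRG1 (0.17) did not pass. Within the 3 scan days HMOX1 stood 1.80, 1.45 and -0.44 from control and FTL 0.68, 0.99 and -0.40, but each day compared different numbers. With number and scan day as blocks the fit called 139 probes, with HMOX1 at 0.92 (adjusted p = 0.0171) and FTL at 0.45 (adjusted p = 0.0147).

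Omitting any single other array left 3 to 28 probes in the block fit at 20 µM FAC, against 10 with all arrays. It called 28 without control replicate 2, 21 without FAC 5 µM replicate 3 and 5 without FAC 20 µM replicate 3. It called 4 without control replicate 3 or 4 or FAC 20 µM replicate 2 or 5, and 3 without control replicate 5 or FAC 20 µM replicate 1.

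**Figure D1:**
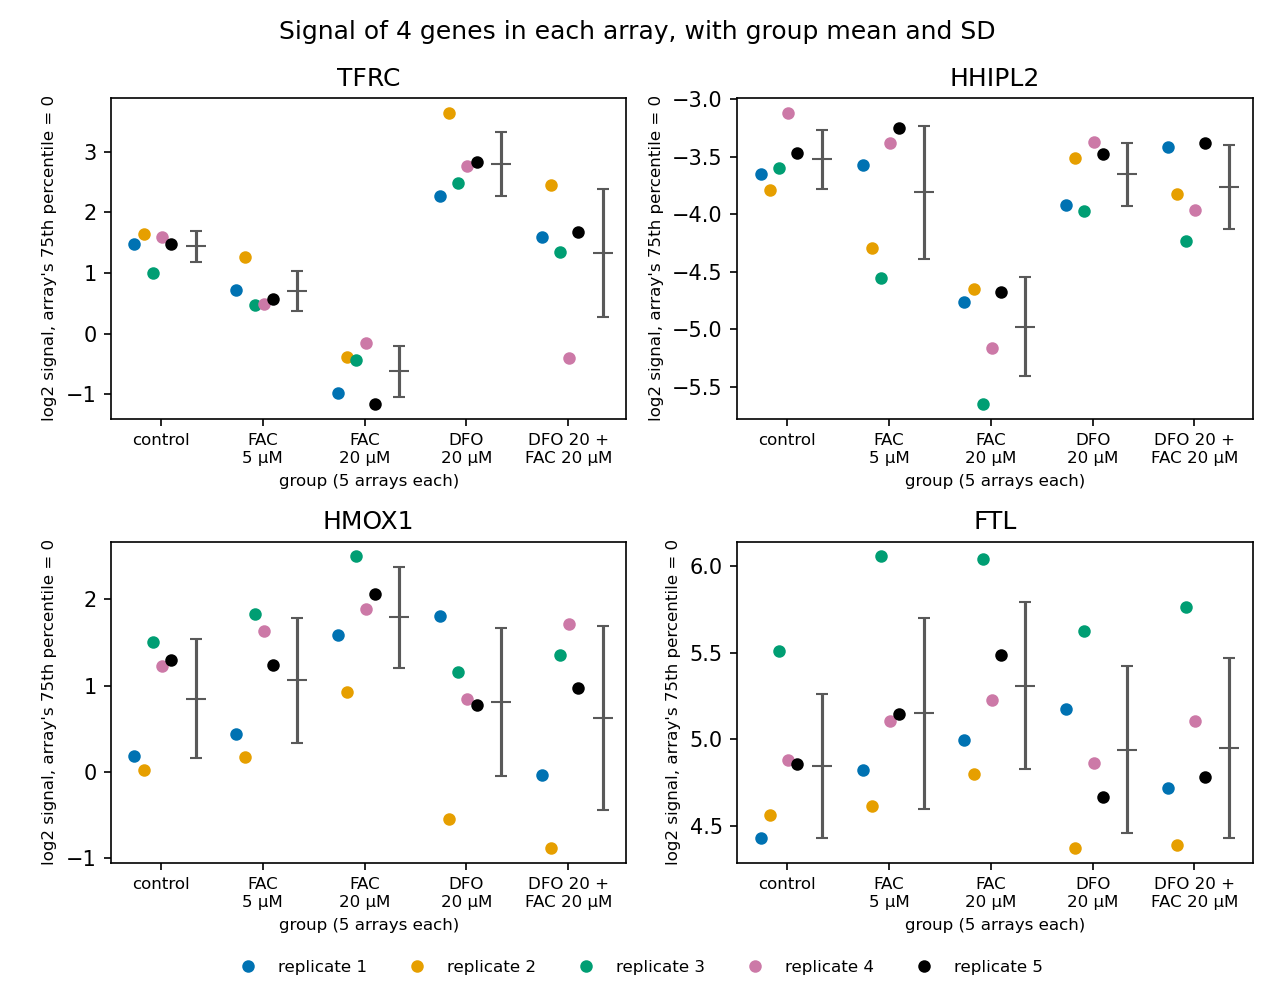
Log2 signal of TFRC, HHIPL2, HMOX1 and FTL on each array (vertical axes; the 75th percentile of each array is 0) in the 5 groups of 5 arrays, coloured by replicate number, with group mean and SD beside the points. TFRC averaged 1.44 in control, 0.71 at 5 µM FAC, -0.62 at 20 µM FAC, 2.80 with DFO and 1.33 with both, and HHIPL2 averaged -3.52, -3.81, -4.98, -3.65 and -3.76.

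Among the gene lists, the one of metallothioneins, which bind zinc and copper, and 2 zinc exporters was higher at 20 µM FAC (median 0.32, 13 of 13 members; camera adjusted p = 3.25e-08, and 0.146 with an estimated correlation). Without DFO replicate 1, 3 of them rose, MT1E (0.35), MT1L (0.34) and MT1B (0.31), and 8 rose adjusted over the list alone. Whether their probes tell these related genes apart was not tested, so which of them changed is uncertain. Targets of the hypoxia-inducible factor were higher (median 0.20, 31 of 33; adjusted p = 2.31e-05, and 0.552 with an estimated correlation). None of them passed singly and 3 rose adjusted over the list alone, with NDRG1 at 0.17 and FAM162A at 0.31. Glycolytic enzymes were higher (median 0.14, 14 of 15; adjusted p = 0.00335, and 0.552 with an estimated correlation), and so were ribosomal proteins (median 0.087, 26 of 26; adjusted p = 9.13e-05, and 0.562 with an estimated correlation). No member of either list passed, and under quantile scaling neither list was called (adjusted p = 0.135 and 0.913), with a ribosomal median of 0.0015.

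TGF-beta and BMP pathway genes were lower (median -0.16, 20 of 25; camera adjusted p = 9.13e-05, and 0.146 with an estimated correlation). Without DFO replicate 1, 3 fell and 7 fell adjusted over the list alone, with the BMP targets ID3 (-0.54) and SMAD6 (-0.50) among both. With the replicate block and an estimated correlation the adjusted p of this list was 0.00372, and 0.0136 when DFO replicate 1 was also omitted. Hedgehog genes were lower (median -0.18, 12 of 14; adjusted p = 9.13e-05, and 0.0476 with an estimated correlation), but HHIPL2 was the single member that fell, over all genes and adjusted over the list alone. HHIPL2 was put on the list because the series title names it, and without it the list had adjusted p = 0.00761, and 0.146 with an estimated correlation. Collagen and matrix genes were lower (median -0.12, 21 of 29; adjusted p = 0.00335, and 0.146 with an estimated correlation). Of these 1 fell, and adjusted over the list alone 3 fell and 1 rose, the collagen crosslinker LOX (0.63).

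Interferon-response genes were lower (median -0.30, 25 of 27; camera adjusted p = 0.000214, and 0.562 with an estimated correlation). Without DFO replicate 1, 6 fell, such as MX2 (-0.67) and OAS2 (-0.47), and ISG20 rose (0.40), and 17 fell adjusted over the list alone. Within replicate numbers 1 to 5 the interferon median was -0.57, -0.19, -0.46, -0.39 and -0.066, below 0 in each. Within the 3 scan days, which compare different numbers, it was 0.21, 0.22 and -1.19. Metallothioneins were higher in 5 of 5 numbers, ribosomal proteins higher and the TGF-beta and BMP, hedgehog and matrix lists lower in 4 of 5. Hypoxia (0.24, -0.10, 0.77, 0.099 and -0.048) and glycolysis (0.23, -0.14, 0.35, -0.011 and 0.22) were higher in 3 of 5. All 8 lists stayed called with number and scan day as blocks together (adjusted p from 4.42e-09 to 0.0166).

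Of the 38 list calls in all comparisons, 1, hedgehog at 20 µM FAC, held with an estimated correlation. fry, which tests whether a list moves on balance one way, or in either direction, and compares it with no other genes, called 0.

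The osteoblast list was not called at 20 µM FAC (median -0.041, 14 of 25 lower; camera adjusted p = 0.216), though its median was below 0 in 5 of 5 numbers. Without DFO replicate 1 the type I collagen chain COL1A2 (-0.32), osteoblast cadherin CDH11 (-0.34) and the receptor FGFR2 (-0.43) fell, and 7 members fell adjusted over the list alone. The secreted Wnt target CCN4 fell (-0.43) in a Wnt list with a median of -0.056. In the inflammatory list (median 0.12) 2 genes rose, and adjusted over the list alone 7 rose and 3 fell. The iron import list, which holds TFRC, had a median of 0.012 and a mean of -0.15. The iron storage list, with HMOX1 and FTL risen, had a median of 0.016 (-0.023 under quantile scaling).

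No other list was called at 20 µM FAC without the block or with the replicate block. The heat shock list was called, lower than control, with number and scan day as blocks together (median -0.12, camera adjusted p = 0.0181; lower in 4 of 5 numbers). Metabolic and mitochondrial lists had medians of -0.015 (iron-sulfur and haem synthesis), 0.0057 (iron-dependent dioxygenases, where the test leaned down), 0.012 (respiratory chain), 0.052 (cholesterol synthesis) and -0.030 (fatty acid synthesis). Lists of growth and stress had medians of 0.078 (proliferation), 0.017 (DNA replication), 0.052 (p53 targets), 0.054 (NRF2 targets), -0.019 (integrated stress response), -0.096 (heat shock), 0.060 (immediate early genes) and -0.15 (growth factors). The apoptosis and ferroptosis list, which also holds TFRC, had a median of 0.023 and a mean of -0.10, matrix proteases a median of 0.027 and housekeeping genes 0.028. Markers of other cell types had medians of 0.043 (adipocyte), 0.14 (chondrocyte), 0.11 (smooth muscle) and 0.13 (leukocyte, epithelial and endothelial). With normexp those of the adipocyte, chondrocyte and leukocyte lists were -0.028, -0.11 and -0.038.

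DFO was added to 20 µM FAC to set chelation against the effect of iron. TFRC rose by 1.95 over FAC alone (SE 0.32, n = 5 per group; higher in 4 of 5 numbers), with replicate 4 of the combined treatment at -0.40 and the others from 1.35 to 2.45. HHIPL2 rose by 1.21 (SE 0.18; 5 of 5). GFPT2 rose by 0.54 (SE 0.091), and TMEM97 fell by 0.39 (SE 0.052). limma with the replicate block called 7 probes (5 up, 2 down), with adjusted p = 0.0274 for TFRC, 0.0183 for HHIPL2, 0.0328 for GFPT2 and 0.00493 for TMEM97. The other 3 were a probe without a symbol (0.97), a GPR155 probe (0.47) and a CPLANE1 probe (-0.71), both genes named after their values were seen. Of the 7 probes, 6 had also passed at 20 µM FAC against control, each in the opposite direction. Both comparisons use the same FAC arrays, so chance values of those arrays also give opposite signs.

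Without the block limma called 0 probes for DFO added to FAC (793 at an unadjusted p under 0.05), with adjusted p = 0.264 for TFRC and 0.439 for HHIPL2. It called 1 probe when combined replicate 4 was left out. Over all alternatives, most of them without the block, the adjusted p ran from 0.0141 to 1.00 for TFRC and from 0.00207 to 1 for HHIPL2. Within scan days TFRC stood 2.12 and 0.97 and HHIPL2 1.59 and 0.96 above FAC alone, with no array of the combined treatment on the remaining day. With number and scan day as blocks limma called 4 probes, with HHIPL2 at 1.25 (adjusted p = 0.00207), while TFRC (1.87) did not pass (adjusted p = 0.0863). Omitting any array but DFO replicate 1 left 2 to 12 probes in the block fit. It called 12 without FAC 20 µM replicate 4, 11 without combined replicate 4, 4 without FAC 20 µM replicate 2, and 2 without FAC 20 µM replicate 1, 3 or 5 or any other combined replicate.

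Without DFO replicate 1 the block fit called 85 probes for DFO added to FAC (61 up, 24 down; 74 genes). Of these, 64 were shared with the 161 of FAC against control, all 64 with opposite sign. MYOC (0.82), TRIM22 (0.80), PCDH10 (0.76, measured on 3 of 5 arrays with FAC alone), ELANE (0.75), SERPINA3 (0.69), MX2 (0.69), CRISPLD1 (0.68, measured on 4 of these arrays), CMPK2 (0.68), MATN2 (0.62) and RTP4 (0.60) rose. FGFR2 (0.40, adjusted p = 0.0351), SMAD6 (0.50, adjusted p = 0.0399) and STAT2, a transducer of interferon signals (0.43, adjusted p = 0.0268), rose too. CSF2 fell by 2.08 (adjusted p = 0.0179; measured on 4 of 5 arrays of the combined treatment) and HMOX1 by 1.17 (adjusted p = 0.00321), each lower in 5 of 5 numbers. FOLR3 (-0.73), C10orf90 (-0.67), KRT32 (-0.63), KCNK12 (-0.50), MSR1 (-0.46), RUNX1 (-0.45), ABCB9 (-0.45), HECW2 (-0.44), HES7 (-0.42), RNF157 (-0.41) and the cholesterol enzyme EBP (-0.31) fell. FTL stood at -0.36 and did not pass. HMOX1 stood -1.71 and -0.09 from FAC alone within scan days. With number and scan day as blocks the fit called 29 probes, with HMOX1 at -1.10 (adjusted p = 0.0181) and TFRC at 1.83 (adjusted p = 0.0258). Of the 26 genes named for passing, 15 had a change over 1.5 times smaller under some alternative. With normexp CRISPLD1 stood at 0.18, ELANE at 0.20, PCDH10 at 0.16, HES7 at -0.10 and ABCB9 at -0.24, and with slide as a fixed block MSR1 at -0.13 and KRT32 at -0.24.

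**Figure D2:**
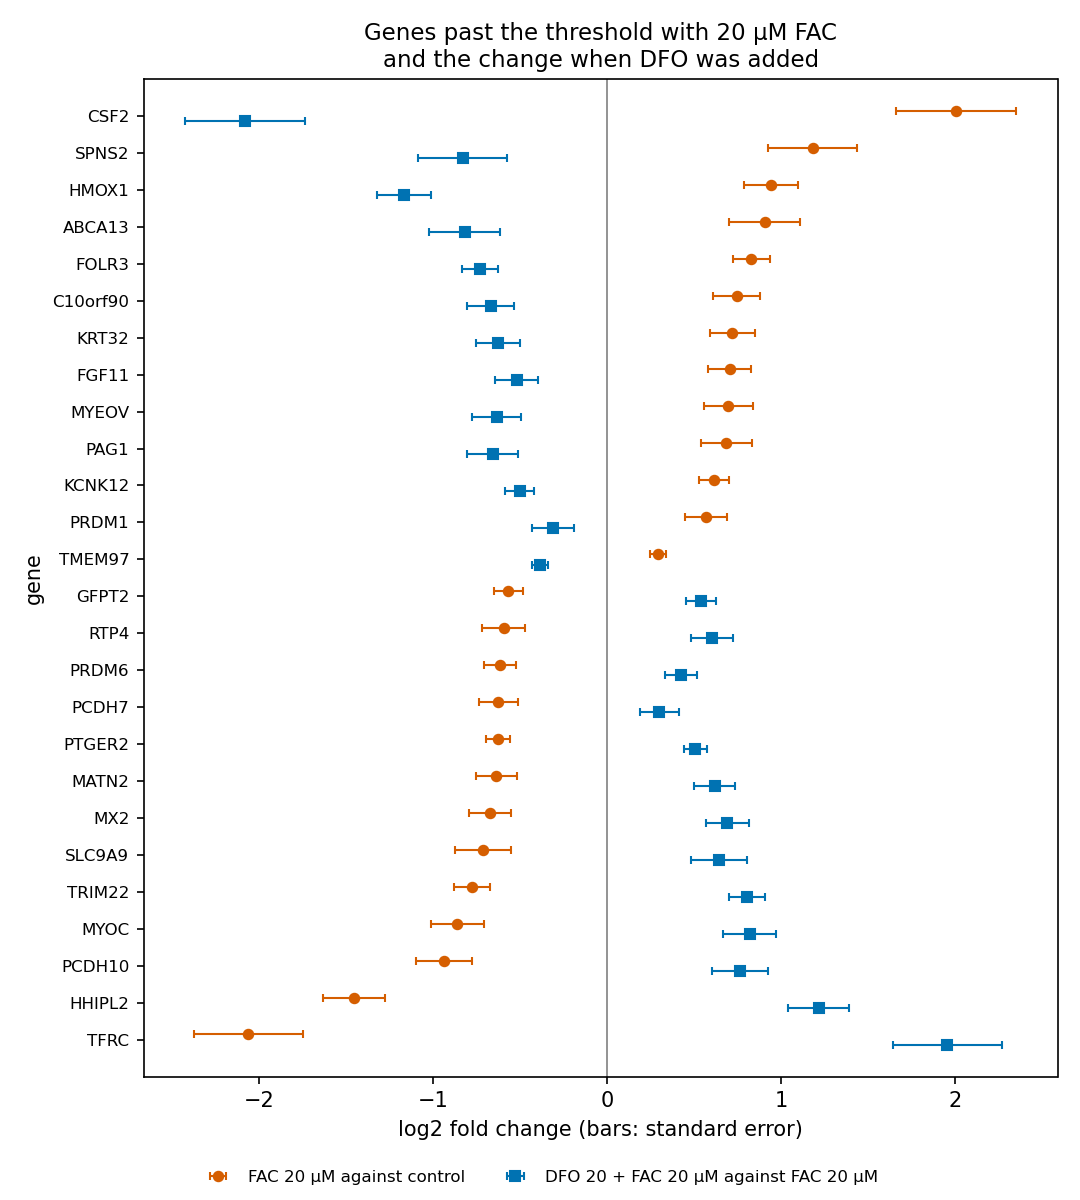
Log2 fold change (horizontal axis, bars: standard error from limma with the replicate block and without DFO replicate 1) of the 26 genes named for passing at 20 µM FAC against control, for that comparison (circles) and for DFO with FAC against FAC alone (squares). All 26 had opposite signs in the 2 comparisons, which share the FAC arrays, and 17 also passed in the second.

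Collagen and matrix genes were higher with DFO and FAC than with FAC alone (median 0.14, 23 of 29; camera adjusted p = 0.00702, and 0.220 with an estimated correlation), with 1 gene risen and 5 adjusted over the list alone. Hedgehog genes were higher (median 0.16, 10 of 14; adjusted p = 0.00765, and 0.220 with an estimated correlation), but not without HHIPL2 (adjusted p = 0.0733), their single risen member. The TGF-beta and BMP list was higher (median 0.12, 19 of 25; adjusted p = 0.00766, and 0.598 with an estimated correlation). With the replicate block and an estimated correlation its adjusted p was 0.0246, but the list was not called when DFO replicate 1 was also omitted. SMAD6 rose singly and 7 members adjusted over the list alone. Interferon-response genes were higher (median 0.26, 26 of 27; adjusted p = 0.00122, and 0.855 with an estimated correlation), with 6 risen, and 17 adjusted over the list alone. The interferon list was not called with scan day as a block (adjusted p = 0.0979), but was with number and day as blocks together (adjusted p = 9.68e-05). It was higher in 5 of 5 numbers (0.62, 0.24, 0.36, 0.33 and 0.14), as were the matrix, hedgehog and TGF-beta and BMP lists. Proliferation genes were called lower with the replicate block (median -0.080, adjusted p = 0.00266, and 0.716 with the block and an estimated correlation; lower in 5 of 5 numbers).

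Metallothioneins (median -0.21, 9 of 13; camera adjusted p = 0.0116), hypoxia targets (median -0.13, 27 of 33; adjusted p = 0.00905) and NRF2 targets (median -0.078, 20 of 26; adjusted p = 0.0167) were lower. Cholesterol synthesis (median -0.12, 21 of 24; adjusted p = 0.0473) and ribosomal proteins (median -0.064, 25 of 26; adjusted p = 0.00905) were lower too. All 5 had adjusted p = 0.855 with an estimated correlation. EBP fell in the cholesterol list, with 6 adjusted over the list alone, no member of the others passed, and 5 metallothioneins and 3 NRF2 targets fell adjusted over the list alone. Under quantile scaling, hypoxia was the single one of these 5 lists called, against adjusted p = 0.0617 for metallothioneins and NRF2 targets, 0.109 for cholesterol and 0.381 for ribosomal proteins. Cholesterol synthesis was lower in 5 of 5 replicate numbers and NRF2 targets in 4 of 5. Hypoxia (0.066, -0.21, -0.43, -0.17 and 0.14), metallothioneins (-0.18, 0.059, -0.28, 0.045 and -0.41) and ribosomal proteins (-0.026, -0.11, 0.11, 0.025 and -0.29) were lower in 3 of 5.

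**Figure D3:**
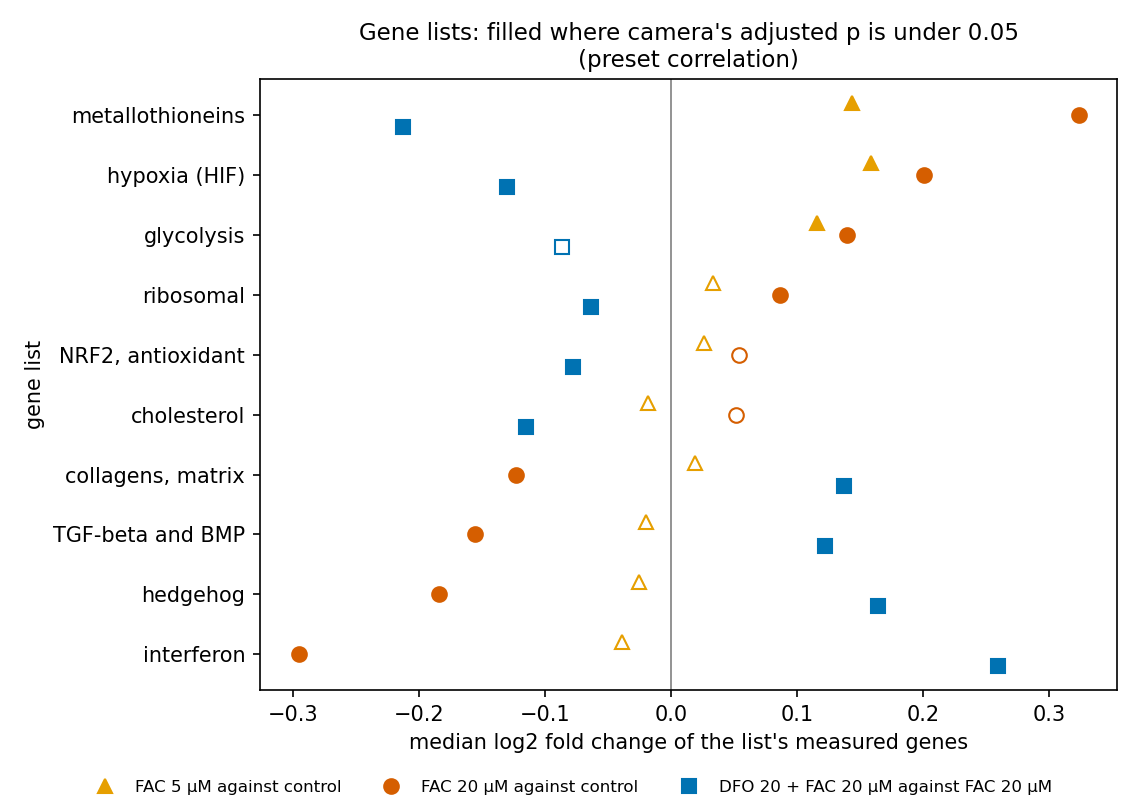
Median log2 fold change (horizontal axis) of the measured genes of the 10 lists called in at least 1 of 3 comparisons, for 5 µM FAC (triangles) and 20 µM FAC (circles) against control and for DFO with FAC against FAC alone (squares), filled where camera's adjusted p was under 0.05 with the preset correlation. Of the filled points only hedgehog at 20 µM FAC stayed called with an estimated correlation, and with normexp the 3 filled triangles moved to -0.31 (metallothioneins), -0.15 (hypoxia) and -0.43 (glycolysis). Circles and squares share the 20 µM FAC arrays, and triangles and circles share the control arrays.

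Between the iron doses HHIPL2 fell by 1.17 from 5 to 20 µM FAC (SE 0.18, n = 5 per group; lower in 5 of 5 numbers). limma with the replicate block called it (adjusted p = 0.0489) and a probe without a symbol (-1.02). Without DFO replicate 1 the block fit called 4 probes, with CCN4 (-0.50) and PTGER2 (-0.42) both fallen at adjusted p = 0.0402. TFRC stood at -1.33 and did not pass (adjusted p = 0.413 with the block). Without the block limma called 0 probes (380 at an unadjusted p under 0.05). With number and scan day as blocks limma called 2 probes, HHIPL2 among them (adjusted p = 0.00323). Over the alternatives, most of them without the block, the adjusted p of HHIPL2 ran from 0.00323 to 1 and those of CCN4 and PTGER2 from 0.0402 to 1. The block fit called 3 probes without combined replicate 4 and 1 without most other single arrays. Within scan days HHIPL2 stood -1.34, -0.98 and -1.23 and TFRC -1.57, -1.17 and -1.03 from 5 µM FAC.

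The TGF-beta and BMP list was lower at the higher dose (median -0.14, 21 of 25; camera adjusted p = 9.80e-05, and 0.101 with an estimated correlation). With the replicate block and an estimated correlation its adjusted p was 0.00118, and 0.00612 when DFO replicate 1 was also omitted. No member passed over all genes, 7 fell adjusted over the list alone, SMAD6 stood at -0.48, and the list was lower in 5 of 5 numbers (-0.17, -0.16, -0.082, -0.12 and -0.31). Matrix (median -0.11; adjusted p = 0.000486, and 0.0710 with an estimated correlation) and hedgehog genes (median -0.13; adjusted p = 0.000731, 0.0230 without HHIPL2, and 0.0710 with an estimated correlation) were lower. Interferon-response genes were lower too (median -0.27; adjusted p = 0.00149, and 0.828 with an estimated correlation). The matrix, hedgehog and interferon lists were each lower in 5 of 5 numbers. Metallothioneins were higher (median 0.16; adjusted p = 0.00417, and 0.671 with an estimated correlation). Ribosomal proteins (median 0.047; adjusted p = 0.00434) and DNA replication genes (median 0.054; adjusted p = 0.0206) were higher, both at adjusted p = 0.828 with an estimated correlation and 0.0889 under quantile scaling. The proliferation (median 0.063, adjusted p = 0.0396, and 0.785 with the block and an estimated correlation) and cholesterol lists (median 0.076, adjusted p = 0.00487, and 0.581 likewise) were called higher with the replicate block. The metallothionein, DNA replication and cholesterol lists were higher in 4 of 5 numbers, and the ribosomal and proliferation lists in 3 of 5. With normexp the median of all genes stood at -0.14 in this comparison, and the matrix and interferon medians were 0.32 and 0.20.

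At 5 µM FAC no gene passed against control. TFRC stood at -0.73 (SE 0.35, n = 5 per group; lower in 5 of 5 numbers; exact permutation p = 0.0159, and 0.153 adjusted over the family), with -1.15, -0.61 and -0.64 within scan days. HHIPL2 stood at -0.29, FTL at 0.30 (higher in 5 of 5) and HMOX1 at 0.21. limma called 0 probes without the block (363 at an unadjusted p under 0.05) and 0 with it (929), and the block fit 1 without control replicate 5. The genes with the smallest p included ANO7 (0.77, measured on 4 control arrays), UPK3B (0.46), RNF32-DT (0.33), ZNF260 (-0.26) and PUM3 (-0.30). Others were at the edge of detection, with GPR50 (1.07), SPI1 (1.05) and SPRN (1.28) measured on 2, 3 and 2 control arrays. H2AB2 and TMEM190, measured on no control array, did not pass either. With lower control values raised to the lowest signal well above background, their means stood 1.59-fold and 1.41-fold higher.

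Hypoxia targets were higher as a list at 5 µM FAC (median 0.16, 32 of 33; camera adjusted p = 0.000265, and 0.768 with an estimated correlation). Metallothioneins (median 0.14, 13 of 13; adjusted p = 0.00153) and glycolytic enzymes (median 0.12, 13 of 15; adjusted p = 0.0274) were higher too, both at adjusted p = 0.766 with an estimated correlation. No member passed, and under quantile scaling metallothioneins (adjusted p = 0.0534) and glycolysis (0.109) were not called. With normexp, where the median of all genes stood at 0.12 here, the 3 medians were -0.15, -0.31 and -0.43. Metallothioneins were higher in 5 of 5 replicate numbers. Hypoxia targets were higher in 2 of 5 (-0.00053, -0.068, 0.82, -0.13 and 0.14), so number 3 carried most of that shift, and glycolysis was higher in 3 of 5 (0.11, -0.063, 0.38, -0.034 and 0.11). All 3 lists stayed called with number and scan day as blocks together (adjusted p from 0.000155 to 0.0174). DNA replication genes were called lower with the replicate block (median -0.023, adjusted p = 0.0365, and 0.755 with the block and an estimated correlation).

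DFO alone, a test of iron depletion, gave the highest mean TFRC signal of the 5 groups (2.80 ± 0.52 SD, n = 5). It stood 1.36 above control (SE 0.35; higher in 5 of 5 numbers; exact permutation p = 0.00794, and 0.102 adjusted over the family), with 1.42, 1.07 and 1.48 within scan days. limma called 0 probes (193 at an unadjusted p under 0.05), and the block fit 1 without combined replicate 4. ANKFN1 (0.76), TPPP3 (0.60), TSSK6 (0.47), PLEKHS1 (0.46, measured on 3 control arrays), the histone demethylase KDM4B (0.28), APLP1 (0.26), MED28 (0.31), KLHL23 (-0.29) and MARCHF3 (-0.80) were among the genes with the smallest p, and the hypoxia-inducible DDIT4 stood at 0.40. Interferon-response genes were higher (median 0.25, 27 of 27; camera adjusted p = 0.000216, and 0.835 with an estimated correlation). Cholesterol synthesis (median -0.12, 22 of 24; adjusted p = 0.00239, and 0.835 with an estimated correlation) and proliferation genes (median -0.067, 27 of 29; adjusted p = 0.0162, and 0.892 with an estimated correlation) were lower. No member of these lists passed. With the replicate block and without DFO replicate 1 the interferon and proliferation lists were not called (adjusted p = 0.691 and 0.730). Within numbers 1 to 5 the interferon median was 1.02, 0.068, -0.19, 0.037 and 0.30, that of proliferation -0.40, 0.029, -0.044, -0.045 and 0.10, and that of cholesterol -0.40, -0.020, -0.19, -0.079 and -0.029, where number 1 holds that array.

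Cells given DFO with FAC were also set against control. TFRC stood at -0.11 (1.33 ± 1.05 against 1.44 ± 0.26 SD, n = 5), HHIPL2 at -0.24 and HMOX1 at -0.23. limma called 0 probes (219 at an unadjusted p under 0.05), which does not show that the groups were equal. ZC3H12D (1.17, measured on 3 control arrays), OR1D2 (0.90, measured on 1), LRCH1 (-0.55), PKIB (-0.88), TPTE2P6 (0.41), CLEC4G (0.45, measured on 4), CATSPERD (0.30), KIF26A (0.40) and ISM2 (0.49, measured on 3) were among the genes with the smallest p. Without the block metallothioneins were the 1 list called, higher than control (median 0.11, 12 of 13; camera adjusted p = 0.000734, and 0.925 with an estimated correlation), at 0.13 on both scan days that had both groups and higher in 3 of 5 replicate numbers (0.15, -0.019, 0.18, 0.28 and -0.025). The lists of cholesterol synthesis (median -0.085, camera adjusted p = 4.79e-06) and fatty acid synthesis (median -0.043, adjusted p = 0.00436) were called with the replicate block, both lower in 4 of 5 numbers and at adjusted p = 0.507 with the block and an estimated correlation.

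Against DFO alone, the combined treatment gave a TFRC difference of -1.47 (lower in 5 of 5 numbers; exact permutation p = 0.0159, and 0.153 adjusted over the family), and -0.73 and -2.17 within scan days. limma called 0 probes (167 at an unadjusted p under 0.05). Metallothioneins were higher (median 0.10, 12 of 13; camera adjusted p = 0.000243, and 0.966 with an estimated correlation). Interferon-response genes were lower (median -0.21, 26 of 27; adjusted p = 0.000243, and 0.966 with an estimated correlation), but not with the replicate block and without DFO replicate 1 (adjusted p = 0.886).

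Over the 5 groups at once, limma's F test called 1 probe, TFRC (271 at an unadjusted p under 0.05). Whether iron acted differently with and without DFO was tested as an interaction, in which limma called 0 probes (279 at an unadjusted p under 0.05). Across 13996 genes, which are not independent replicates, the effect of 20 µM FAC alone correlated with that of FAC in the presence of DFO at r = 0.197 (Spearman rho = 0.135, covariance 0.0045), but at r = 0.0288 without number 3. The effects of 5 and 20 µM FAC correlated at r = 0.552 (rho = 0.525, covariance 0.013), but they share control arrays. Simulated unchanged groups sharing controls gave r = 0.502 (covariance 0.010), and with the experiments split between the doses the median r was 0.040 (-0.22 to 0.23).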

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

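The tests of array quality, slide, swapped numbers and foreign RNA for DFO replicate 1 and that of array quality for TFRC were chosen only after the result was seen.

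Single arrays stood apart from their group in 4 of 75 groups of values, and chance gives about 1 in 20. TFRC was 0.996 in control replicate 3, below the other controls (gap over range 0.741). COL1A1 was 4.35 in the array of 5 µM FAC, replicate 3 (0.752). Control replicate 4 had 65.2% of its spots well above background (0.789), the lowest of the 25 arrays. DFO replicate 1 had 5 kept probes at the signal floor (0.8), against 0 to 2 on the other arrays.

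In 5 gene lists the effect of iron differed with and without DFO (camera on the interaction). Hypoxia targets moved by a median of 0.20 with FAC alone and 0.021 with DFO present (difference -0.19, adjusted p = 0.00445, and 0.839 with an estimated correlation). Glycolytic enzymes moved by 0.14 and -0.0016 (difference -0.10, adjusted p = 0.0276, and 0.706 with an estimated correlation), and ribosomal proteins by 0.087 and -0.012 (difference -0.092, adjusted p = 0.00727, and 0.845 with an estimated correlation). TGF-beta and BMP genes moved by -0.16 and -0.019 (difference 0.12, adjusted p = 0.0236, and 0.706 with an estimated correlation), and NRF2 targets by 0.054 and -0.080 (difference -0.12, adjusted p = 0.0251, and 0.706 with an estimated correlation). With the replicate block and an estimated correlation the TGF-beta and BMP difference had adjusted p = 0.0424. But DFO replicate 1 does not follow its number, and with that array also omitted this difference was not called. Under quantile scaling hypoxia was the 1 list of these called, and with scan day as a block 3 of the 5 were. With number and day as blocks together 4 were, without glycolysis (adjusted p = 0.269). No gene passed in the interaction. The values with DFO present rest in part on DFO replicate 1. With the block and without that array the differences were -0.27 (hypoxia), -0.19 (glycolysis), -0.080 (ribosomal proteins) and 0.10 (TGF-beta and BMP). At the preset correlation camera still called these 4, but NRF2 targets stood at -0.050 and were not called (adjusted p = 0.234). With an estimated correlation 0 of the 5 lists were called in that fit. No other explanation of these differences was tested.

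DFO replicate 1 stood apart from the other arrays of its number, with a mean correlation of deviations of 0.012 with them, against at least 0.316 for each of the other 24 arrays. The tables argue against poor array quality as the whole cause, since its deviations followed the arrays numbered 3 at a mean of 0.297, though it had the most kept probes at the floor (5) and 302 outlier spots, next to the highest of 303, so lower quality stays open in part. Its deviations followed the other 2 arrays of its slide at 0.0943. Control replicate 1 is 1 of those 2, and arrays on the same slide shared 0.10 in general, so this cannot decide on slide or scan day. The tables argue against numbers 1 and 3 swapped within DFO, since replicate 3 followed number 3 more than number 1 by 0.599. They also argue against RNA of 1 of the other 4 experiments. The 0.297 of replicate 1 is below 0.486, the lowest for arrays numbered 3 outside the DFO group. RNA from outside these experiments or a mixture stays open, as does a different course of that culture, and no biological explanation was tested.

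TFRC in replicate 4 of DFO with FAC (-0.40) lay near the arrays with FAC alone (mean -0.62), away from the other 4 (1.35 to 2.45). Iron-only RNA under this label would put the other called genes at the level of FAC alone too. They stood at a share of 0.314 of the difference between FAC alone and control. The other 4 numbers had shares from -0.154 to 0.215. This leans against iron-only RNA as the whole cause. But these genes were picked on the same control and FAC arrays, which lowers such a share by itself, so it is not excluded. HMOX1 stood at 1.71 there, against 1.23 in control and 1.89 with FAC in number 4. HHIPL2 stood at -3.96, against -3.11 and -5.16. Poor array quality is argued against by 68.8% of spots well above background, within the 65.2% to 72.5% of the other arrays, though it had the most outlier spots (303). Chelation that failed in part in this culture stays open and was not tested.

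Probes called at 20 µM FAC without DFO replicate 1 also moved part of the way at 5 µM FAC, by 0.18 on average in the direction at 20 µM, against 0.52 at 20 µM, and above 0 in 5 of 5 numbers. Both averages share the control arrays, so chance values of those arrays give such a shift too. Against DFO with FAC, which shares no array, the 5 µM group stood 0.0993 further in that direction, above 0 in 4 of 5 numbers, with the lowest at -0.034 (exact sign-flip p = 0.125, where 0.0625 is the smallest that 5 numbers can give). Against DFO alone, which shares no array either, it stood 0.25 further, above 0 in 5 of 5 numbers (lowest 0.082, exact sign-flip p = 0.0625), but that difference also holds any effect of DFO itself (-0.074 from control, above 0 in 2 of 5). It also includes DFO replicate 1, which does not follow its number, so 1 of these 5 pairs is in doubt. These values go with a graded response to iron, but 5 numbers cannot give a p under 0.05 and 1 of them went against it in the first comparison, so chance values of the FAC and control arrays stay open beside it.

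Other splits of the arrays were used to ask whether chance groupings give as many probes. Without the block the real count was 0 in each of the 7 comparisons and the interaction, so all 100 of 100 splits gave as many whatever the data, and these splits decide nothing about chance. The highest other splits gave 1 (5 µM FAC), 898 (20 µM FAC), 41 (DFO), 1 (DFO with FAC against FAC), 0 (against control), 461 (against DFO) and 1 (FAC doses). For the interaction the highest other was 1. The F test called 1 probe, and 6 of 100 assignments, the real one included, gave as many (highest other 558), so chance cannot be excluded. At an unadjusted p under 0.05, 20 µM FAC gave 587 probes, and 49 of 100 splits gave as many (highest other 3870), and DFO with FAC against FAC gave 793, with 44 of 100 (highest other 3460), so chance cannot be excluded for these counts either. Splits that call many genes point to a structure of the samples, here the replicate numbers. The real split parts 5 pairs of same-numbered arrays, the split with 898 calls parts 3, and those with the most unadjusted probes part 1. Among other splits that part 5 pairs the most unadjusted probes were 1138 for 20 µM FAC and 977 for DFO with FAC against FAC.

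With the block, 16 ways of swapping labels within numbers are too few for a share under 0.05. The real count was 10 for 20 µM FAC (highest other 1) and 7 for DFO with FAC against FAC (highest other 1), and without DFO replicate 1 it was 161 (highest other 3) and 85 (highest other 1). The FAC doses gave 2 (highest other 0), and 5 µM FAC and DFO with FAC against control gave 0 (highest other 0), where all 16 swaps give as many whatever the data. Omitting that DFO array was chosen after the data were seen.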

How the results depend on the processing

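All settings that leave out the DFO group, DFO replicate 1 or DFO with FAC replicate 2 by name, that join the replicate block to only the compared arrays, to an estimated correlation or to scan day, and the scan-day block for lists were chosen after the data were seen. Counts are probes called by limma, against 0 without a block in every pairwise comparison and 1 in the F test.

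For 20 µM FAC against control the replicate block gave 10, and 161 without DFO replicate 1, 8 without DFO with FAC replicate 2, 116 without the DFO group and 1 with the compared arrays alone. With number and scan day as blocks it gave 4, and 139 without DFO replicate 1. Without the block, the filter on all 25 arrays, 1 probe per gene, the trended robust prior and array weights gave 2 each, and scan day as a block, the compared arrays alone and omitting DFO with FAC replicate 2 gave 1 each. For DFO with FAC against FAC the block gave 7, and in the same 3 omissions 85, 2 and 49, and number with day gave 4, and 29 without DFO replicate 1. For the FAC doses it gave 2, then 4, 1 and 1, and number with day 2 and 2. At 5 µM FAC slide as a fixed block gave 2 and the block without the DFO group 1. The F test gave 8 with the block, 51 and 6 in the first 2 omissions, 5 and 29 with number and day, and 2 with a fixed slide block or array weights. With all arrays the block changed no other count, comparisons with DFO alone included, and 20 of 25 arrays correlated best with their own number, but not control 4, FAC 5 µM replicate 5, FAC 20 µM replicates 1 and 5 and DFO 1. HHIPL2 at 20 µM FAC (-1.46, adjusted p = 0.0633) passed at -1.46 with the filter on all 25 arrays (0.0489), 1 probe per gene (0.0418), the robust prior (0.0396) and the block (0.00193), and with the block in the 3 omissions (0.00135, 0.00372 and 0.00579). It also passed at -1.43 with scan day (0.0270) or array weights (0.0181) and, with number and day, at -1.43 (0.000195, and 0.000430 without DFO replicate 1), and its adjusted p ran from 0.000195 to 1 over all settings. It had the same direction in every setting. The first 2 of these test fewer probes. The replicate block left the change at -1.46 and lowered the median residual SD over probes by 30.0%. The cause was not tested for the rest.

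Omitting 1 of the arrays compared, without the block, left 0 in every comparison, except DFO with FAC against FAC (0 to 1, with 1 without its replicate 4), and gave 1 to 2 in the F test (2 without FAC 5 µM replicate 3). HHIPL2 ran from -1.54 to -1.29. The correlation of the iron effects with and without DFO ran from 0.0288 (without number 3) to 0.245, and that of the 2 FAC doses from 0.463 to 0.634. The correlation over genes past the threshold was not run, since no gene passed without the block.

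Of 38 list calls, 1 was kept with an estimated correlation, 0 with fry, 0 with fry in either direction, 23 under quantile scaling, 5 with the block and an estimated correlation and 2 of these without DFO replicate 1. The block kept 38 (45 called in all), slide 38 (39), number and day together 37 (50), scan day 35 (40), the mean of probes 35 (37) and the block without DFO replicate 1 34 (55). The cause was not tested. Of 1071 named gene values, 0 reversed direction from or to a call. No gene passed without the block, so this could count only turns to a call in another setting. The sign turned without a call in 151 of them with normexp and in 134 with slide as a fixed block. In any other setting it turned in at most 56. FGF11 at 20 µM FAC, at -0.053, was among those with normexp. Signal over background limits the dim genes, since a change from below background is seen only in part. HHIPL2, well above background on all 25 arrays, stood at -0.72 under normexp. That correction adds an offset of 50 to every signal, which by itself shrinks the changes of dim probes such as this one. How much of the smaller change came from the offset was not tested.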

Other observations

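The genes and lists named here for differing between replicate numbers were chosen only after their values were seen. The replicate numbers differed more than the treatments. The secreted glycoprotein CHI3L1 ranged over 7.50 on the log2 scale between numbers (adjusted p = 2.70e-07 from limma), the endothelin EDN2 over 5.18, MYBPH over 4.73, the crosslinking enzyme TGM2 over 4.70, FOS over 4.69, the chemokine CXCL8 over 4.57 and the iron exporter SLC40A1 over 4.21. CHI3L1, EDN2, MYBPH, TGM2 and SLC40A1 were lowest in number 2 and highest in number 3. CXCL8 was highest in number 2 and lowest in number 4. Across numbers 1 to 5 the median of interferon-response genes stood at -0.40, -0.59, 0.45, 0.23 and 0.30, with 26 of 27 members differing. Cholesterol synthesis ranged over 0.81 (22 of 24 members), immediate early genes over 0.67 and inflammatory genes over 0.59.

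Scan day accounted for less, with 133 of 21940 probes differing by day in limma. The second principal component (19.8% of the variance) followed the number (R2 0.93), and arrays on the same slide shared a correlation of 0.10. Markers of other cell types were in part well above background on all 25 arrays. These were 5 of 12 adipocyte, 6 of 13 chondrocyte, 9 of 12 smooth muscle and 11 of 16 leukocyte, epithelial and endothelial genes, and EPCAM and CDH1 were above it on none.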
